A study of Mus musculus with 24 samples.

How the data were processed

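The series holds 24 RNA-seq libraries of back skin epidermis from 8-week-old male C57BL/6 mice with a keratin 14 Cre knockout of Bmal1, 4 animals at each of ZT0, ZT4, ZT8, ZT12, ZT16 and ZT20. Per the labels' protocols, the epidermis was freed with dispase, a stranded kit for polyadenylated RNA was used and single reads of 51 bases were sequenced. The submitters' processing notes name Trimmomatic 0.36, HISAT2 2.2.1, SAMtools 1.3.1, featureCounts 1.6.0, edgeR and the build mm10, without their order or settings, and the strand setting of the counting is not given in the sources used here. Per the series design text, rhythms were compared with those of WT epidermis by dryR, a method that fits a cosine curve in each group and weighs models in which groups share, lose or change the rhythm.

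The 1 file used is the table of that comparison, with 17721 genes. For each gene the deposited table gives a score, from 0 to 1, for each of 5 rhythm models, a weight made from the Bayesian information criterion, and likewise for 2 models of the mean. Mean levels are log2 values as the authors deposited them, and how libraries were scaled to one another is not given in the sources used here. The column label of the side that is not WT was taken as EpiKO because the comparison has 2 sides. Which model is which was read from the parameters: model 1 has no amplitude in either genotype, 2 has one in EpiKO, 3 in WT, 4 has equal amplitudes in both and 5 has unequal ones. The deposited amplitude equals 2 times the root of the summed squares of both coefficients, within a tolerance of 1e-06, for 5062 EpiKO and 5914 WT rhythms, so it is the peak-to-trough height in log2, and folds are 2 to that power. The largest weight of model 4, 0.98, corresponds under the information criterion to 47.96 libraries, close to the 48 of a design with 24 in each genotype. There were no counts or values per library, so depth is unknown, replicates could not be compared, and the planned tests of rhythm in EpiKO across libraries were not run.

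A gene was assigned to the model with the largest weight when that weight was at least 0.5. The 35 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Symbols matched 17720 of 17721 identifiers, and 700 of 709 list entries matched a gene of the table. Lists with at least 5 assigned members were compared with other assigned genes by two-sided Fisher's exact tests per class, 132 in all. Concentration of peak times was tested one-sided against 10000 random draws of genes rhythmic in that genotype, 41 tests in all, and mean differences by Fisher's exact tests in each direction, 68 in all. Each family of tests was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Amplitudes of genes with different rhythms were compared by an exact binomial sign test.

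Named genes are Arntl and the measured core clock genes, and the 8 genes per rhythmic class with the largest amplitude at or above the median mean level of 7.61 (log2), leaving out predicted genes. Added to these are up to 4 members per list with a called class or peak time and per list of another cell type, taken by amplitude, and the 6 genes with the largest mean difference each way. Not every gene that the rule takes is named. Krt27, Krt71 and Krt14 are named in the closing section after their values were seen. Positions come from GENCODE mouse M21, whose assembly is mm10.

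To gauge reads that fit several genes, the share of 51-base windows of each gene's transcripts found in transcripts of another gene, on either strand, was counted, and a limit of 5% was set after seeing the data. Antisense overlaps matter where counting ignores strand. In checks with lists drawn from these genes, 50 of 50 lists with a planted effect were called by each list test. The planted effects were strong, so this says little about power for weaker ones. Of the tests of random lists, 2.62% and 3.97% had a p below the threshold. The model choice was tested on 20000 simulated genes per pattern with 48 libraries and independent normal noise of known variance. Alternatives were other weight limits of none, 0.4 and 0.8, a minimum amplitude of 0.25 (log2), leaving out genes under the 0.25 quantile of mean expression, expression-matched random lists, leaving out the core clock genes, and for means a minimum difference of 0.5 and centring on the median. Added after seeing the data were the genes with few shared windows, sums of model weights and the different-rhythm genes outside the cell division lists. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used.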

Results

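The epidermal transcriptome was profiled over the day in mice that lacked Bmal1 (gene symbol Arntl), a core activator of the circadian clock, in the epidermis through a Cre recombinase driven by the keratin 14 promoter. These mice are called EpiKO here. Back skin of 24 male mice, 4 at each of 6 times 4 h apart from zeitgeber time (ZT) 0, when the lights came on, was collected under 12 h of light and 12 h of dark. The measurements used here are 1 table of 17721 genes in which the authors had fitted the daily rhythm of each gene in EpiKO and in wild-type (WT) epidermis. The WT libraries are not samples of this series. The table holds no values per library, so the depth of each library is unknown, no spread between animals can be given, and genotype cannot be separated from any difference in how the 2 sets of libraries were made. Weights quoted below are the probabilities the authors' fit gave to a model, not p-values, and fold amplitudes are peak over trough of the fitted curve.

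The first question was what became of the clock genes themselves. Of 18 core clock genes assigned to a class, 10 were rhythmic in WT only and 5 had different rhythms in the 2 genotypes. Per1 was the single gene with the same rhythm in both, and Bhlhe40 and Nfil3 had none. Both the WT-only share (adjusted p = 2.3e-05) and the share with different rhythms (adjusted p = 0.00239) exceeded those of other genes (two-sided Fisher's exact tests). Among genes that share little sequence with others, the second did not pass (3 of 14 genes, adjusted p = 0.107, with a range of 0.00187 to 0.107 over the alternatives).

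Arntl (ENSMUSG00000055116; chromosome 7, 113207465 to 113314126, mm10) cycled 4.65-fold in WT with a peak at ZT22.7 and was assigned no rhythm in EpiKO, with a weight of 0.882 in the authors' deposited table. Its mean level of 9.65 in EpiKO and 9.50 in WT (log2) in the authors' deposited table sums reads over the whole gene, so it does not show how much of the deleted part was transcribed. Dbp, a transcription factor activated directly by BMAL1 (chromosome 7, 45705088 to 45710203), cycled 42.8-fold in WT and was called flat in EpiKO, where its mean was lower by a difference of -2.49 (log2) in the authors' deposited table. Others in the WT-only class were Ciart (18.1-fold in WT), Per3 (10.8-fold), Tef (7.77-fold), Npas2 (6.50-fold), Cry1 (5.88-fold), Cry2 (2.92-fold) and Hlf (2.01-fold) in the authors' deposited table. Mean levels differed both ways in the authors' deposited table, with Per3 at -2.26 and Ciart at -1.47 but Cry1 at 1.87 and Npas2 at 1.88 (log2, EpiKO minus WT).

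Rhythms remained in part of the repressor arm. Per2 (chromosome 1, 91415982 to 91459324) cycled 69.6-fold in WT and 2.91-fold in EpiKO with peaks at ZT13.1 and ZT12.3 in the authors' deposited table. Nr1d1, which encodes REV-ERB alpha, went from 17.2-fold to 3.08-fold, and Nr1d2 from 6.25-fold to 1.66-fold in the authors' deposited table. The mean of Nr1d1 differed by -4.18 and that of Nr1d2 by -2.45 (log2, EpiKO minus WT) in the authors' deposited table. Bhlhe41 (3.47-fold in WT, 2.60-fold in EpiKO) and Clock (1.27-fold and 1.16-fold) made up the rest of the class in the authors' deposited table. Over the 5 core clock genes with different rhythms, peak times differed between genotypes by a median of 5.81 h in either direction. Of the 5, 1 peaked later in EpiKO, so the near-equal peak times of Per2 do not stand for this group. Per1 kept a fitted 3.11-fold rhythm with a peak at ZT9.89 in both genotypes in the authors' deposited table. Rora was left unassigned, with a weight of 0.487 in the authors' deposited table. Dbp, Ciart, Bhlhe41 and Nr1d1 share 16.2%, 11.6%, 16.3% and 7.24% of their 51-base windows with other genes, so their levels are less certain.

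**Figure D1:**
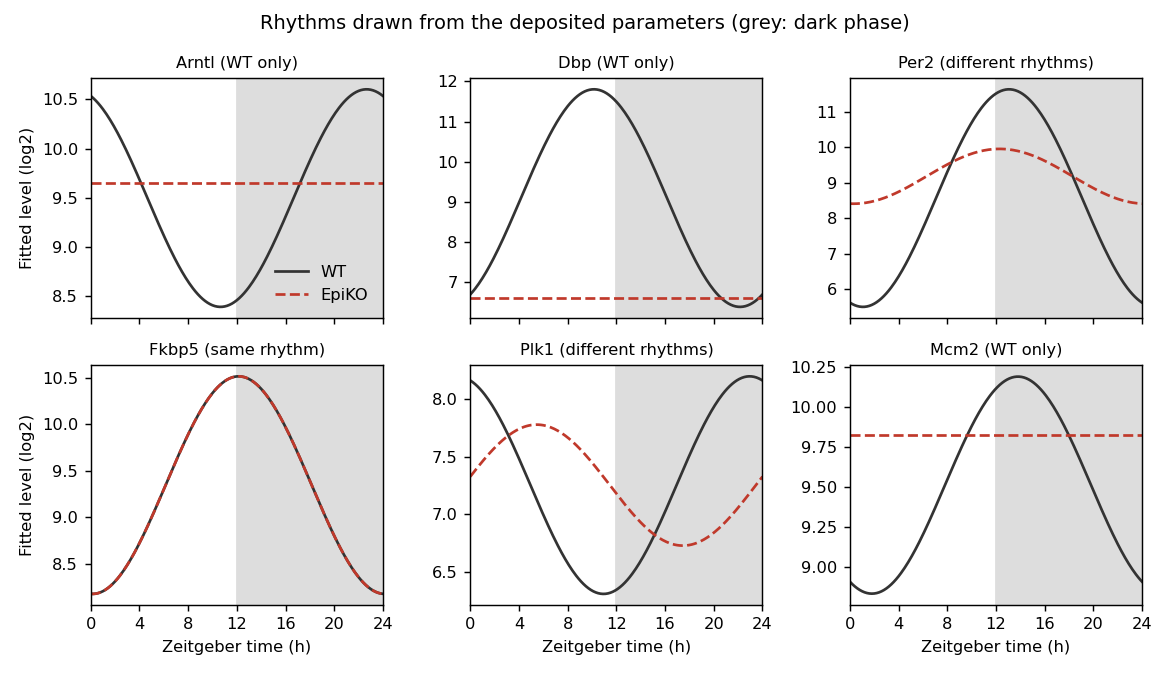
Curves drawn from the authors' deposited parameters for 6 genes, with zeitgeber time in hours on the x axis and the fitted level (log2) on the y axis, WT solid and EpiKO dashed. Arntl, Dbp and Mcm2 were assigned no rhythm in EpiKO, Per2 is damped from 69.6-fold to 2.91-fold, Fkbp5 has 1 shared curve and Plk1 peaks at ZT22.9 in WT and ZT5.46 in EpiKO.

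Across the table, more genes were assigned the same rhythm in both genotypes than a rhythm in WT only. Of 15723 genes with a model weight of at least 0.5, 10045 had no rhythm, 2954 had the same rhythm in both genotypes, 1490 were rhythmic in WT only, 764 in EpiKO only, and 470 had different rhythms. The same-rhythm class made up 60.1% of the 4914 genes rhythmic in WT. The simulated data had 48 libraries and independent normal noise of known variance, so rates in the real libraries may differ. There, 1.22% of flat genes were assigned to EpiKO only and 1.41% to WT only. That would be 216 and 250 genes if all 17721 genes were flat, and fewer flat genes otherwise. Of simulated genes with the same rhythm in both and a peak-to-trough height of 1 SD, 5.28% were assigned to EpiKO only, 5.13% to WT only and 28.3% to the same rhythm. Single-genotype classes can therefore hold weak shared rhythms. At 2 SD, 89.7% were assigned the same rhythm. The reverse also occurred, since of simulated genes rhythmic in WT only at 2 SD, 5.41% were assigned the same rhythm and 14.35% no rhythm. A limit of 0.8 on the weight left 250 EpiKO-only, 659 WT-only, 1501 same-rhythm and 286 different-rhythm genes. Sums of model weights over all genes, added after seeing the data, were larger, at 1595, 2400, 3765 and 875 for these classes.

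Amplitudes are ranked here among genes at or above the median mean level. Of those with the same rhythm, the largest amplitudes belonged to Fkbp5 (5.06-fold, peak at ZT12.2), Tsc22d3 (4.07-fold, ZT11.9) and Zbtb16 (3.94-fold, ZT10.5), 3 glucocorticoid-induced genes, in the authors' deposited table. They were followed by Txnip (3.34-fold), Per1, Glul (2.97-fold), Tent5b (2.87-fold) and Wee1, a kinase that holds back entry into mitosis (2.69-fold), with peaks between ZT9.60 and ZT11.1 in the authors' deposited table. Outside the core clock list, the WT-only class had Ttc9 among its 8 largest at that level, with 4.51-fold at ZT22.8 in the authors' deposited table. The EpiKO-only genes at that level with the largest amplitudes were Fosl1 (12.8-fold, ZT5.41), an AP-1 subunit, Thbs1 (7.96-fold, ZT6.21) and the orphan nuclear receptor Nr4a2 (6.13-fold, ZT4.35) in the authors' deposited table. Arid5a (3.72-fold), Mir22hg (2.85-fold), Nfkbiz (2.83-fold) and Gas2l3 (2.49-fold) peaked between ZT4.36 and ZT6.11 in EpiKO, and Serpina3j (3.47-fold) at ZT13.3, in the authors' deposited table. Fosl1 (0.552), Thbs1 (0.509), Arid5a (0.56) and Mir22hg (0.554) had weights just above the limit in the authors' deposited table, and 52.5% of the windows of Fosl1 were shared with another gene.

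Peak times were spread over the day in the WT-only class, where the 6 windows of 4 h held 174 to 303 genes each. Same-rhythm genes gathered in the windows from ZT4 to ZT8 (743 genes) and ZT16 to ZT20 (862 genes). EpiKO-only genes had their largest numbers in the same windows, with 178 and 222 of 764 genes. The share of genes with a peak in the light phase was 44.1% for EpiKO only and 47.5% for WT only, which did not differ (two-sided Fisher's exact test, p = 0.129).

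**Figure D2:**
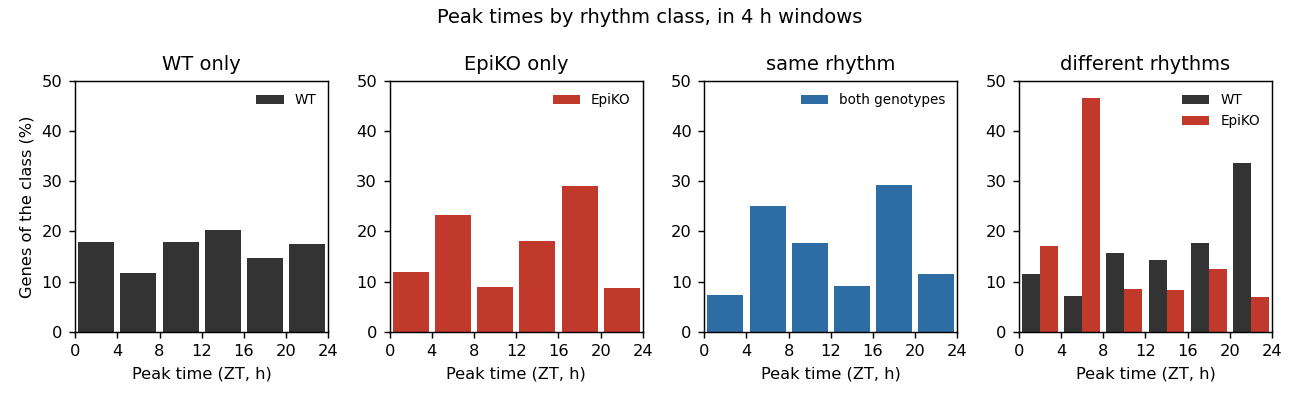
Share of the genes in a rhythm class (%, y axis) that peak in each 4 h window of zeitgeber time (x axis). WT-only genes hold 11.7% to 20.3% per window, and 46.6% of the different-rhythm genes peak from ZT4 to ZT8 in EpiKO.

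Mitosis genes cycled in both genotypes at different times of day. Of 30 mitosis genes, 28 had different rhythms (adjusted p = 5.07e-39), 1 was rhythmic in WT only and 1 in EpiKO only. The 28 genes peaked at a mean of ZT22.8 in WT, late in the dark phase, and ZT5.90 in EpiKO, in the light phase. Each peaked later in EpiKO, by 6.12 to 8.24 h with a mean of 7.05 h. Their median fold amplitude was 2.79 in WT and 2.03 in EpiKO, and 24 of the 28 were lower in EpiKO (exact sign test, p = 0.00018). Nusap1 went from 3.85-fold at ZT22.5 to 2.26-fold at ZT5.19 in the authors' deposited table. The mitotic kinase Plk1 went from 3.72-fold at ZT22.9 to 2.08-fold at ZT5.46, and the checkpoint kinase Bub1 from 3.26-fold at ZT21.1 to 1.97-fold at ZT5.17, in the authors' deposited table. Ccnb2, a B-type cyclin, peaked at ZT23.9 in WT and ZT7.11 in EpiKO, and Ndc80 was 1 of the 4 with a larger amplitude in EpiKO (2.61-fold against 2.23-fold) in the authors' deposited table.

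DNA replication genes were rhythmic in WT in 36 of 36 assigned members. Of these 26 were assigned a rhythm in WT only (adjusted p = 8.84e-18) and 10 different rhythms (adjusted p = 1.73e-06). With a weight of at least 0.8 the WT-only number was 16 of 23, and over all 38 measured members the model weights summed to 22.2 for WT only and 14.1 for different rhythms, so part of the list was not clearly without rhythm in EpiKO. The WT peaks of the 26 averaged ZT14.3, early in the dark phase, with a median amplitude of 1.88-fold. The 10 others peaked at a mean of ZT15.4 in WT and ZT2.11 in EpiKO, with median amplitudes of 2.15-fold and 1.42-fold, and 10 of 10 were lower in EpiKO (exact sign test, p = 0.00195). Orc1 of the origin recognition complex (3.60-fold in WT), Ccne2 (2.63-fold) and the helicase subunits Mcm2 (2.57-fold) and Mcm3 (2.53-fold) were in the WT-only group in the authors' deposited table. Mcm10 went from 2.79-fold at ZT16.7 to 1.66-fold at ZT2.96, and Cdc6 from 2.42-fold at ZT15.4 to 1.51-fold at ZT0.704, in the authors' deposited table. Cdt1 (2.57-fold to 1.44-fold) and Dtl (2.25-fold to 1.45-fold) were also in this group in the authors' deposited table. No member of the mitosis or DNA replication list had the same rhythm in both genotypes, 0 of 30 (adjusted p = 0.0437) and 0 of 36 (adjusted p = 0.0135). These absences did not pass under some alternatives, with adjusted p from 0.00526 to 0.175 for mitosis and 0.000817 to 0.164 for DNA replication.

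**Figure D3:**
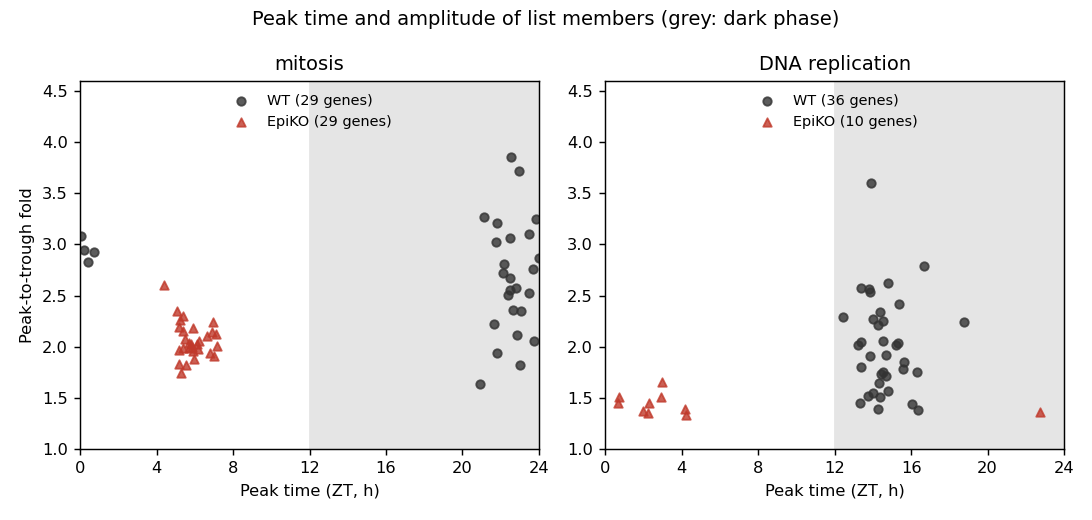
Peak time (ZT, h, x axis) and peak-to-trough fold (y axis, starting at 1) of the assigned rhythmic members of the mitosis and DNA replication lists, 1 symbol per gene and genotype, from the authors' deposited parameters. Mitosis genes lie around ZT22.8 in WT and ZT5.87 in EpiKO, and 36 DNA replication genes were assigned a rhythm in WT against 10 in EpiKO.

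Other gene groups kept their rhythm. Of 42 ribosomal protein genes 39 had the same rhythm in both genotypes (adjusted p = 1.63e-23), with peaks at a mean of ZT11.8 and a median amplitude of 1.17-fold. Among them were Rpl11 (1.22-fold), Rpl3 (1.22-fold) and Rpl32 (1.21-fold) in the authors' deposited table. With a minimum amplitude of 0.25 (log2), 9 of 42 were in the class and the call was lost (adjusted p = 0.521, with a range of 7.67e-27 to 0.521 over the alternatives). Only 5 of 53 measured ribosomal protein genes have few shared windows, so this call could not be tested without shared reads. Ribosome biogenesis genes shared a rhythm in 22 of 28 cases (adjusted p = 3.8e-10), with a mean peak at ZT16.7. Rrs1 (1.39-fold), Rrp1b (1.39-fold), Heatr1 (1.37-fold) and Nolc1 (1.34-fold) had the largest amplitudes of that group in the authors' deposited table. Genes of the unfolded protein response, which serve protein folding in the endoplasmic reticulum, did so in 13 of 17 cases (adjusted p = 8.69e-06), at a mean of ZT20.1. Sdf2l1 (2.40-fold), Creld2 (1.92-fold), the chaperones Calr (1.71-fold) and Hsp90b1 (1.62-fold) led it in the authors' deposited table.

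Glucocorticoid response genes shared a rhythm in 7 of 11 cases (adjusted p = 0.0175), at a mean of ZT11.3 and with a median amplitude of 3.11-fold. This call was lost against expression-matched random lists (adjusted p = 0.333), without the core clock genes, which removes Per1 (adjusted p = 0.0624), and without genes under the 0.25 quantile of expression (adjusted p = 0.0813), within a range of 0.00187 to 0.333 over the alternatives. Heat shock genes did not pass (9 of 20, adjusted p = 0.0661), but passed with a minimum amplitude of 0.25 (8 of 20, adjusted p = 0.0246, with a range of 0.0246 to 1 over the alternatives). Growth and translation genes (7 of 13, adjusted p = 0.0534) and fasting response genes (7 of 15, adjusted p = 0.121) did not pass. Of 33 lists tested 26 had no call in any class, among them immediate early genes with 2 of 17 assigned members rhythmic and interferon response genes with 1 of 16.

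**Figure D4:**
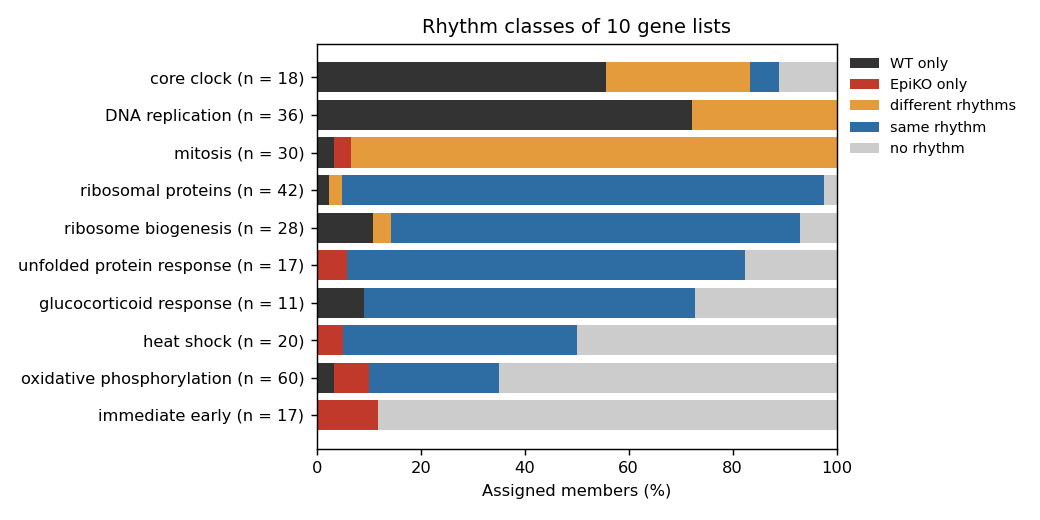
Share of assigned members (%, x axis) in each rhythm class for 10 gene lists, with the number of assigned members beside each name. The same-rhythm class holds 92.9% of ribosomal protein genes, and the different-rhythm class 93.3% of mitosis genes.

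Members of a list often peaked together. Of 41 tests of a list in a genotype 26 were more concentrated than random draws of rhythmic genes (permutation test), and p = 0.0001 is the smallest these draws can give. A gene assigned the same rhythm has 1 fitted curve and counts in both genotypes, so for lists made up mostly of such genes the near-equal peak times and the second passing test are set by the model. Such genes were 9 of the 9 heat shock genes rhythmic in WT and 9 of the 10 in EpiKO, and numbered 7 for cholesterol synthesis, 5 for melanocyte, 15 for oxidative phosphorylation, 7 for glucocorticoid response, 13 for unfolded protein response, 22 for ribosome biogenesis and 39 for ribosomal protein genes. Heat shock genes peaked at ZT19.0 in WT and ZT18.5 in EpiKO (adjusted p = 0.000373 and 0.00191), with Hsph1 at 2.28-fold, Fkbp4 at 1.51-fold and Ahsa1 at 1.45-fold in both genotypes in the authors' deposited table. Cholesterol synthesis genes peaked at ZT2.18 and ZT3.06 (adjusted p = 0.00338 and 0.00898), among them Sc5d (1.41-fold in both) and Fdps (1.43-fold in both) in the authors' deposited table. Melanocyte genes peaked at ZT16.9 and ZT17.5 (adjusted p = 0.00898 and 0.000373), with the pigment genes Tyrp1 (4.38-fold) and Dct (2.65-fold) sharing a rhythm in the authors' deposited table. Oxidative phosphorylation genes peaked at ZT20.6 and ZT19.5 (adjusted p = 0.000946 and 0.000373), with amplitudes such as 1.31-fold for Ndufab1 in the authors' deposited table. Fasting response genes passed in EpiKO (ZT9.36, adjusted p = 0.00752) and not in WT (adjusted p = 0.065). The core clock (ZT11.6, adjusted p = 0.0318), glycolysis (ZT17.1, adjusted p = 0.0397), growth and translation (ZT13.9, adjusted p = 0.0182), autophagy and lysosome (ZT8.93, adjusted p = 0.0106) and basal keratinocyte genes (ZT8.54, adjusted p = 0.0321) passed in WT. The same 5 lists did not pass in EpiKO, where the core clock had 6 rhythmic members, and the difference between genotypes was not tested. All 7 growth and translation genes rhythmic in WT were assigned the same rhythm, and 1 EpiKO-only gene joined them in EpiKO. Of the members rhythmic in EpiKO, 7 of 8 autophagy and lysosome, 5 of 7 basal keratinocyte and 7 of 9 fasting response genes had the same rhythm. A pass in 1 genotype therefore does not show that clustering was lost or gained. Among genes with few shared windows, the WT calls of the core clock (adjusted p = 0.187), autophagy and lysosome (0.0573), basal keratinocyte (0.124) and oxidative phosphorylation genes (0.0555) were lost. The EpiKO call of oxidative phosphorylation genes was lost there too (permutation test, 6 rhythmic members, adjusted p = 0.0573). The WT call of growth and translation was lost with no minimum weight (0.0633) and with a minimum amplitude of 0.25 (0.0622).

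The next question was how amplitudes and peak times differed in the genes with different rhythms. Of 3424 genes assigned as rhythmic in both genotypes, 2954 were assigned 1 shared curve, which sets equal amplitude and peak time. What follows holds only for the class chosen because its rhythms differ. Of the 470 genes with different rhythms 340 had a smaller amplitude in EpiKO (exact sign test, p = 1.02e-22), with a median ratio of 0.752. Peaks lay 3 to 12 h later in EpiKO for 327 of them. Outside the mitosis and DNA replication lists, 306 of 432 genes had the smaller amplitude in EpiKO (exact sign test, p = 2.29e-18). These 432 still include cell division genes that are on neither list, such as Aspm. The count therefore cannot show whether smaller amplitudes extend beyond cell division genes. Besides the clock genes, different-rhythm genes with large amplitudes included Aspm, a spindle protein (4.26-fold in WT, 2.31-fold in EpiKO), Serpina3b (3.72-fold and 1.81-fold) and the taurine transporter Slc6a6 (3.63-fold and 1.68-fold) in the authors' deposited table. Genes of a pathway are not independent replicates, so these p-values and those of the lists are smaller than independent genes would give.

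Mean levels differed between EpiKO and WT for 12426 genes, 5797 higher and 6629 lower in EpiKO. Larger differences were less balanced, with 2080 genes higher and 4204 lower by at least 0.5 (log2), and 802 higher and 2982 lower by at least 1. Genes that share much sequence with others were lower. Among genes at or above the median mean level, the median difference (log2, EpiKO minus WT) was 0.11 for 3300 genes with no shared 51-base window, 0 for 3322 with up to 5% shared, -0.07 for 1756 with up to 25%, -0.82 for 381 with up to 50% and -1.91 for 102 genes with over 50% shared. Among the 12885 genes with at most 5% of windows shared, 4848 were higher and 3771 lower, and 646 were higher and 1341 lower by at least 1 (log2). At or above the median mean level, differences of that size were higher in 2.64% and lower in 0.758% of genes with no shared window, and higher in 2.68% and lower in 3.82% of those with up to 5% shared.

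**Figure D5:**
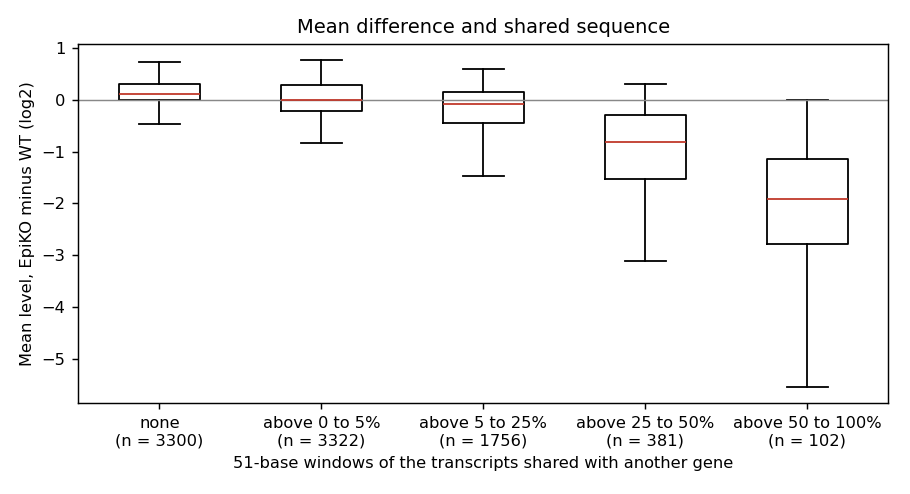
Difference in mean level (log2, EpiKO minus WT, y axis) of genes at or above the median mean level, grouped by the share of their 51-base windows found in another gene (x axis). Boxes span the quartiles with the median as a line and whiskers reach the 5th and 95th percentiles, and medians go from 0.11 with none shared to -1.91 above 50%.

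The 6 genes with the largest differences downward were Rpl23a (-10.62), Krt6b (-9.64), Dsg1c (-8.57), Igf2bp3 (-8.30), Krt6a (-7.93) and Rpl24 (-7.73) in the authors' deposited table, and each shares 18.1% to 80.7% of its windows. Those upward included Rpl39 (5.12), Sdhd (4.58), Dnase2a (4.58), Nxf1 (3.76) and Glrx5 (2.96) in the authors' deposited table. Of these, Dnase2a shares 27.4% of its windows and Sdhd 0%, so a difference of this size also occurred in a gene without shared windows. Its cause was not tested. Ribosomal protein genes were lower in 44 of 53 cases (adjusted p = 7.62e-10) and higher in 6, against 17.3 expected (adjusted p = 0.00795), and of the 5 with few shared windows 1 was lower (adjusted p = 1, with a range of 1.64e-14 to 1 over the alternatives). Oxidative phosphorylation genes were higher in 49 of 70 cases (adjusted p = 7.11e-09), by a median of 0.25, but in 8 of 70 by at least 0.5 (adjusted p = 1, with a range of 4.9e-12 to 1 over the alternatives). Mitosis genes were higher in 20 of 30 cases (adjusted p = 0.00424), by a median of 0.37. Across genes with no shared window the mean difference also followed GC content (Spearman's rho -0.43 across genes). The list tests of mean levels were not matched for GC content, so whether these small shifts depend on it was not tested. None of 19 immediate early genes was higher (adjusted p = 0.0095), which did not pass for differences of at least 0.5 (adjusted p = 0.443, with a range of 0.00112 to 0.443 over the alternatives).

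Markers of other cells differed as well. Langerhans and dendritic cell genes were higher in EpiKO in 13 of 15 cases (adjusted p = 0.000563), by a median of 1.08, among them H2-Aa (1.25) and Tyrobp (1.08) in the authors' deposited table. The macrophage receptor gene Csf1r went the other way (-1.66) in the authors' deposited table. T lymphocyte genes were lower in 0 of 16 cases (adjusted p = 0.00961) and higher in 10, which did not pass (adjusted p = 0.0882), with a median difference of 0.64 and Thy1 at 1.09 in the authors' deposited table. The absence of lower T lymphocyte genes did not pass among genes with few shared windows (0 of 13, adjusted p = 0.119, with a range of 0.00961 to 0.119 over the alternatives). Fibroblast genes were higher in 10 of 15 cases without passing (adjusted p = 0.075), with Sparc at 1.57, Col6a1 at 1.18, Fn1 at 0.46 and Fbln1 at -0.48 in the authors' deposited table. Sebaceous gland genes were higher in 9 of 14 cases (adjusted p = 0.0997). Hair follicle genes were lower in 8 of 19 (adjusted p = 0.827), among them Krt25 (-6.14) and Lhx2 (-0.77) in the authors' deposited table. Muscle genes were lower in 8 of 14 (adjusted p = 0.377), with Acta1 at 2.21 in EpiKO and 9.90 in WT in the authors' deposited table. Endothelial genes were higher in 5 of 11 cases (adjusted p = 0.588), adipocyte genes in 2 of 10 (adjusted p = 0.7) and melanocyte genes in 0 of 11 (adjusted p = 0.0997).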

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

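The tests of explanations in this part were chosen after the result was seen. The rhythm differed between EpiKO and WT in 3 lists more often than in other genes. In the core clock list 10 genes were rhythmic in WT only and 5 had different rhythms. In the DNA replication list the numbers were 26 and 10, and in the mitosis list 28 genes had different rhythms.

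The later peak of mitosis genes in EpiKO was weighed against technical explanations. EpiKO sampling times that were off as a whole would displace other rhythms too, yet 86.3% of the 3424 genes assigned as rhythmic in both genotypes had the same rhythm, which argues against it. Growing hair follicles in 1 genotype could bring dividing cells with another rhythm. Of the inner root sheath keratins Krt25, Krt27 and Krt71, the median level in the higher genotype lay -10.96 (log2) from that of Krt14, but Krt25 alone was higher in WT by over 1, so this stays open. An effect of the missing epidermal clock, which the design names, and differences between the 2 sets of libraries also stay open, since no values per library were held.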

How the results depend on the processing

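No paired analysis was possible because the table holds fitted parameters per genotype and no values per library. For the same reason the planned tests of rhythm in EpiKO were not run, with their alternatives of a replicate block, a DESeq2 likelihood ratio test, DESeq2 size factors, no filter on low values, another pseudocount, time as a factor and leave-one-out, and limits set by depth are unknown. Of 341 alternative values over 54 results 301 kept their side of the threshold, or for counts stayed near the reported count, and 0 reversed. A reversal was recorded only where an alternative passed the threshold in the other direction. Counts and peak-time tests could not reverse in this sense, and mean peak hours were not compared across the alternatives. Of the 301, 18 could not have moved, since the median mean difference was 0 before centring and the chosen mean model always had a weight of at least 0.5, which leaves 283. Stricter limits leave fewer genes by construction, and for the lists below the cause was not tested. Ranges in parentheses run over the alternatives of a result.

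A weight of at least 0.8 left 6253 genes without rhythm, 250 EpiKO only, 659 WT only, 1501 with the same rhythm and 286 with different rhythms. Leaving out genes under the 0.25 quantile of expression left 6062 without rhythm. Sums of model weights, added after seeing the data, gave 1595, 2400 and 875 for EpiKO only, WT only and different rhythms.

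The call on the absence of the same rhythm was lost for DNA replication (0.000817 to 0.164) at a weight of 0.8 (adjusted p = 0.164) and an amplitude of 0.25 (0.116), and for mitosis (0.00526 to 0.175) at these settings (0.0572 and 0.175) and without core clock genes (0.0584). The glucocorticoid response call (0.00187 to 0.333) was lost without low expression (0.0813), against expression-matched lists (0.333) and without core clock genes (0.0624). An amplitude of 0.25 ended the ribosomal protein call (0.521, range 7.67e-27 to 0.521) and gave heat shock one (0.0246, range 0.0246 to 1). WT peak times of growth and translation (0.0202 to 0.0633) lost their call with no minimum weight (0.0633) and the minimum amplitude (0.0622), and those of basal keratinocyte genes (0.00325 to 0.135) with the latter (0.135).

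Among genes with few shared windows, added after seeing the data, calls were lost for the same-rhythm class of DNA replication (0.107) and mitosis (0.133) and different rhythms of the core clock (0.107, range 0.00187 to 0.107). WT peak times lost theirs for the core clock (0.187, range 0.0195 to 0.187), oxidative phosphorylation (0.0555, range 0.00045 to 0.0555), autophagy and lysosome (0.0573, range 0.00567 to 0.0573) and basal keratinocyte genes (0.124), as did the EpiKO peak time of oxidative phosphorylation (0.0573, range 0.000631 to 0.0573). In that set 3771 genes were lower in EpiKO, and calls were lost for ribosomal proteins being lower (1, range 1.64e-14 to 1) and seldom higher (1, range 0.000148 to 1) and for T lymphocyte genes being seldom lower (0.119, range 0.00961 to 0.119).

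With a mean difference of at least 0.5, 2080 genes were higher and 4204 lower, and calls were lost for oxidative phosphorylation genes being higher (1, range 4.9e-12 to 1), for ribosomal proteins (0.322) and immediate early genes (0.443, range 0.00112 to 0.443) being seldom higher and for T lymphocyte genes being seldom lower (0.113).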

Other observations

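In this part, the GC-content test and the test of histone genes with few shared windows were set before their results were seen, and the other tests were chosen after. The 37 gene families described next were chosen by symbol after the data had been examined, and 15 of 148 class tests passed. Apart from a count of histone genes with few shared windows, family calls were not rerun under the alternatives, expression-matched random lists among them. Whether calls near the threshold depend on expression level was therefore not tested.

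Of the aminoacyl-tRNA synthetases, which load amino acids onto transfer RNA, 10 of 15 assigned members had the same rhythm (Fisher's exact test, adjusted p = 0.0019). Translation initiation factors shared a rhythm in 20 of 46 cases (adjusted p = 0.0042) and mitochondrial ribosome genes in 23 of 67 (adjusted p = 0.0406). Proteasome subunits had no class call, and the 11 rhythmic in WT peaked together at ZT19.2 (adjusted p = 0.00477). The EpiKO peak adds little, since 9 of them were assigned the same rhythm, with 1 fitted curve for both genotypes. Kinesins, motor proteins of which several serve mitosis, had different rhythms in 11 of 32 cases (Fisher's exact test, adjusted p = 8.21e-08). Mean peaks were ZT23.4 over the 16 kinesins rhythmic in WT and ZT5.55 over the 17 rhythmic in EpiKO. Both sets include 5 with the same rhythm. Splicing factors were rhythmic in WT only in 10 of 36 cases (adjusted p = 0.0267), and keratins in EpiKO only in 8 of 43 (adjusted p = 0.0202). The keratin call was not rerun on genes with few shared windows, so what reads shared between genes contribute to it was not tested. Histone genes were rhythmic in WT only in 16 of 52 cases (Fisher's exact test, adjusted p = 0.000551). The 24 histone genes rhythmic in WT, in whichever class, had a mean peak at ZT20.7. The median share of histone gene windows found in another gene was 45.7%. Of the 6 assigned members with few shared windows 0 were in the WT-only class, too few to tell what reads shared between genes contribute. The kit selected polyadenylated RNA, and how much histone RNA it captured is not known. DNA replication genes rhythmic in WT peaked earlier, at a mean of ZT14.6.

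Lower mean levels in EpiKO of genes that share sequence were weighed against GC content and shared reads. Against genes with no shared window in the same of 10 bins of GC content, the median difference of genes with over 50% shared was -2.01 (log2, 95% bootstrap interval -2.39 to -1.68), which argues against GC content as the whole cause, although across genes with no shared window the difference also followed GC content (Spearman's rho -0.43 across genes, which are not independent replicates). If shared reads were counted in WT and not in EpiKO, the difference should fall with log2 of the unshared part at a slope near 1. The slope over 2239 genes was 1.48 (1.24 to 1.74), and its interval passed the upper limit of 1.5 set for that explanation, so shared reads counted differently could not be decided. How the WT libraries were read and counted is not given in the sources used here, and genotype stays open as untested.

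EpiKO-only genes peaked from ZT4 to ZT8 or ZT16 to ZT20 in 52.4% of cases, against 26.4% of WT-only genes and 54.3% of same-rhythm genes, in windows picked because these counts were largest there. If these were shared rhythms missed in WT, genes whose same-rhythm model had a weight under 0.01 should lack the pattern, yet 51.3% of 150 such genes (exact 95% interval 43.0% to 59.6%) peaked there. Reads shared between genes are argued against by 53.3% of 563 EpiKO-only genes with few shared windows, against 26.4% of WT-only genes with few. A candidate explanation is a cue other than the epidermal clock acting on these genes, which no test here addressed, and a difference shared by EpiKO libraries of these times, which would also set peaks 12 h apart, stays open, since values per library were not held.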
